A study of Homo sapiens with 6 samples.

How the data were processed

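RNA was extracted from OCI-LY19 cells and libraries were made with a stranded poly(A) mRNA kit, per the labels' protocols. The 6 libraries fall into 2 groups by their titles: 3 with the non-targeting guide sgNTC1 and 3 with a guide against SETD1B. The submitters' processing notes list CASAVA 1.8, Trimmomatic, HISAT2, featureCounts, DESeq2 and the build hg38, with no role or order; parameters, gene annotation and the strand setting of the counting are not given in the sources used here. The authors deposited a table of raw counts per gene for 26485 genes, of which 8131 had no count in any library. They also deposited a table of log2 normalized counts for 11842 of these genes. Every log2 value equalled the log2 of the count divided by a size factor of its library (largest deviation 5.2e-14), and 64 values that could not be computed were all counts of 0. That table holds no fold change or p-value, so the planned overlap with the authors' calls could not be made and it was used for this check alone. Without a stated strand setting, reads of genes that overlap on opposite strands cannot be told apart, and reads shared between near-identical genes may have been lost or split; 62 genes had counts identical to those of another gene.

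Total counts were 32651772 to 39417394 per library, and the 10 highest genes took 3.46 to 3.89% of them. Pairs of libraries of a group differed by more than counting noise (chi-square per degree of freedom 2.30 to 14.2, against 84.6 to 115 between groups), so all were kept as separate replicates. The common dispersion of 0.00218 gives a coefficient of variation of 4.66% between replicates.

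Genes were tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts: TMM scaling, filterByExpr with a minimum count of 10, robust dispersions and the quasi-likelihood F test, with Benjamini-Hochberg adjustment over 13170 genes and a threshold of 0.05. CPM were computed on the TMM-scaled library sizes. The printed standard error of a log2 fold change is approximate, the change divided by the square root of its F. A fold against a group with 0 counts was computed against a floor of 3 counts over the group, and one against 1 to 3 counts is given with its exact binomial 95% interval. On simulated counts for the same 13170 genes, 46% of 50 genes changed 1.2-fold were recovered, 76% at 1.5-fold, 82% at 2-fold and 98% at 4-fold, with 14 false calls among 12970 unchanged genes.

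Before the data were examined, 28 gene lists, the tests and the alternatives were fixed. The 25 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with adjustment over the lists. Named genes were fixed by rule: SETD1B, SETD1A and KMT2D; the 12 largest increases and 12 largest decreases with an adjusted p under 0.05, a mean CPM of at least 5, no clone-style or pseudogene-style name and no overlap between groups; and in each list up to 4 members with the smallest adjusted p; a few genes that this rule selects are not reported here. The other settings were RLE and upper-quartile scaling, no filter and a filter of CPM of at least 5 in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out, an adjusted p of 0.01, and for lists fry, voom values and an estimated correlation. After the data were seen, a correction for GC content (offsets in 20 bins; 96.6% of genes tested had a value), a run without genes of identical counts, a run without genes of arm 1q and 4 further gene lists were added. Gene positions, lengths and GC content came from a RefSeq and a GENCODE annotation of GRCh38, the assembly also called hg38; 25320 symbols matched and 1165 did not. Summaries and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.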

Results

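The series profiled OCI-LY19, an established diffuse large B cell lymphoma line that already carries a mutation of KMT2D, by poly(A)-selected stranded RNA sequencing. KMT2D and SETD1B both encode enzymes that methylate lysine 4 of histone H3 (H3K4). Isogenic cells were made with CRISPR guides, and 3 libraries from cells with a non-targeting guide (sgNTC1, the control) were set against 3 from a line made with a guide against SETD1B. The question was how gene expression differs when SETD1B is mutated on top of KMT2D. Total counts were 39417394, 34373485 and 36362072 in the control libraries and 32651772, 36837213 and 36968412 in the libraries labelled SETD1B knockout. Each group is represented by 1 guide and 1 line, and the labels do not say whether the replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. Values are mean ± SD CPM, the counts scaled to a common library size (n = 3 libraries per group), and positions are on hg38.

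SETD1B itself (chromosome 12, 121790155 to 121832656) did not lose its transcript. Its counts were 2496, 2326 and 2532 in the control libraries and 2594, 2755 and 3000 in those labelled knockout. The level went from 67.2 ± 3.4 to 78.1 ± 3.4 CPM, a log2 fold change of 0.22 (approximate SE 0.046, adjusted p = 0.00147 by the edgeR quasi-likelihood test), higher in 3 of 3 libraries than in any control. Small insertions or deletions from Cas9 cutting need not lower a transcript's count, so this level does not check the labels, and directions below are those of the libraries labelled knockout. SETD1A, the paralogous methyltransferase (chromosome 16, 30957754 to 30984664), fell from 99.6 ± 3.6 to 81.4 ± 6.5 CPM, a log2 change of -0.29 (SE 0.055, edgeR adjusted p = 0.00113). KMT2D (chromosome 12, 49018978 to 49060794) fell from 244 ± 3.8 to 222 ± 15.2 CPM, a log2 change of -0.14 (SE 0.045, edgeR adjusted p = 0.0226). Both decreases ended once the GC content of genes was corrected for, a check added after the data were seen, with log2 changes of 9.0e-05 for SETD1A and 0.018 for KMT2D (edgeR adjusted p = 0.998 and 0.506). The same correction raised the SETD1B log2 change to 0.43. It removes any shift that genes of like GC content share, whether technical or biological. It therefore cannot tell whether the decreases of SETD1A and KMT2D were a bias. The KMT2D call was also lost without control replicate 1, 2 or 3, at adjusted p = 0.0628, 0.0758 and 0.0913 by edgeR.

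**Figure D1:**
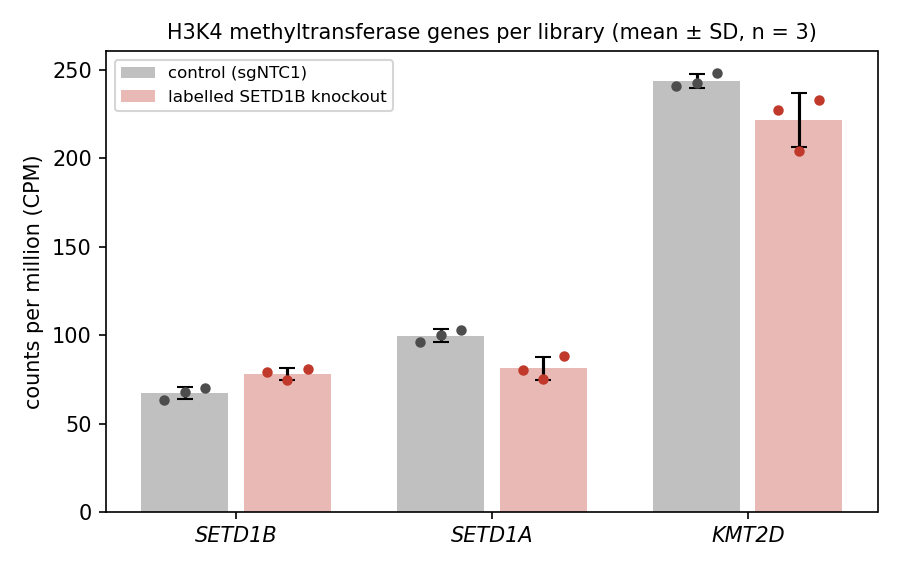
Bars give the mean CPM of SETD1B, SETD1A and KMT2D in control (grey) and knockout-labelled (red) libraries, error bars the SD and points the 3 libraries per group. SETD1B lies at 67.2 CPM in control and 78.1 CPM in knockout-labelled libraries, while SETD1A goes from 99.6 to 81.4 CPM.

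Across the transcriptome the lines differed widely. Of 13170 genes tested, 7957 passed an adjusted p of 0.05 by edgeR, with 3999 higher and 3958 lower in the libraries labelled knockout. A change of at least 2-fold was seen for 1387 of these, 721 higher and 666 lower, and of at least 4-fold for 538. Most changes were smaller, with a median absolute log2 fold change of 0.23 over all genes tested. The 2 groups did not overlap for 67.2% of genes, against 10% by chance, and the first principal component, with 88.3% of the variance, separated them. Requiring a CPM of at least 5 in 3 libraries left 569 genes at 2-fold, 233 higher and 336 lower.

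The genes with the largest increases were nearly silent or low in control cells, with the highest control levels for BCHE (1.05 ± 0.24 CPM) and TBXA2R (0.701 ± 0.033 CPM). CDC42BPB, a kinase acting on the actin cytoskeleton (chromosome 14, 102932380 to 103057549), rose from 0.0380 ± 0.033 to 13.1 ± 1.3 CPM. SEPP1, the gene of selenoprotein P (chromosome 5, 42799880 to 42811892), rose from 0.0727 ± 0.013 to 22.6 ± 0.76 CPM. TNIK, a kinase of the Wnt pathway (chromosome 3, 171058414 to 171460408), rose from 0.0966 ± 0.094 to 10.3 ± 0.47 CPM, and MEGF11 rose from 0.342 ± 0.092 to 18.8 ± 0.98 CPM. KLHL14 went from 0.219 ± 0.026 to 11.6 ± 1.6 CPM and HNRNPLL, a splicing regulator of lymphocytes, from 0.194 ± 0.13 to 10.0 ± 0.31 CPM. ZNF521, a zinc finger cofactor that antagonises EBF1, rose 43.7-fold, TMEM72 50.3-fold, RBMS3 34.5-fold and the axon guidance gene SLIT1 30.0-fold. BCHE (butyrylcholinesterase) rose 25.5-fold and TBXA2R, the thromboxane receptor, 23.6-fold. All 12 had an edgeR adjusted p of 3.97e-09 or lower. They were higher in 3 of 3 libraries, which the rule for naming them required.

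Among the largest decreases, ZNF518B (chromosome 4, 10439880 to 10461365) had 2194 counts over the control libraries and 0 over those labelled knockout, at least 714-fold lower when set against a floor of 3 counts over the group. LCP2, the adaptor SLP-76 of antigen receptor signalling (chromosome 5, 170246233 to 170297777), had 1300 counts in control and 1 in the others, a ratio of 1269 (95% counting interval 227 to 50157). IL7R, the interleukin-7 receptor, fell from 11.1 ± 0.71 to 0.0449 ± 0.041 CPM, and CCR7, a chemokine receptor that guides lymphocytes to lymph nodes, from 19.1 ± 0.37 to 0.393 ± 0.014 CPM. ASS1, the argininosuccinate synthase of arginine synthesis, fell from 36.7 ± 0.27 to 0.432 ± 0.20 CPM. TNRC6C, a component of microRNA silencing, fell 94.9-fold, CWF19L1 65.6-fold, OVCH2 54.5-fold and SAG, the arrestin of the retina, 50.6-fold. SDK2 fell 49.5-fold, CHST11 40.6-fold and the interferon-inducible PYHIN1 31.0-fold. OVCH2 adjoins CYB5R2 on chromosome 11, which fell 14.8-fold. Intervals and floors cover counting error only.

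Genes of the long arm of chromosome 1 (1q) were shifted as a block. Over 440 expressed 1q genes the median log2 fold change was 0.45 (quartiles 0.27 and 0.62), a 1.37-fold higher level, and 372 rose while 25 fell by edgeR. Over 557 genes of the short arm the median was -0.01, with 156 higher and 182 lower. The shift was present in each of the 3 libraries labelled knockout, at 0.45 to 0.48 relative to the other genes, and the control libraries lay between -0.01 and 0.01. Named genes on 1q include RBBP5, KDM5B, RFX5, BTG2, ASPM, SDHC, CD48 and PYHIN1, of which KDM5B, CD48 and PYHIN1 fell. This arm was examined after the data were seen.

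**Figure D2:**
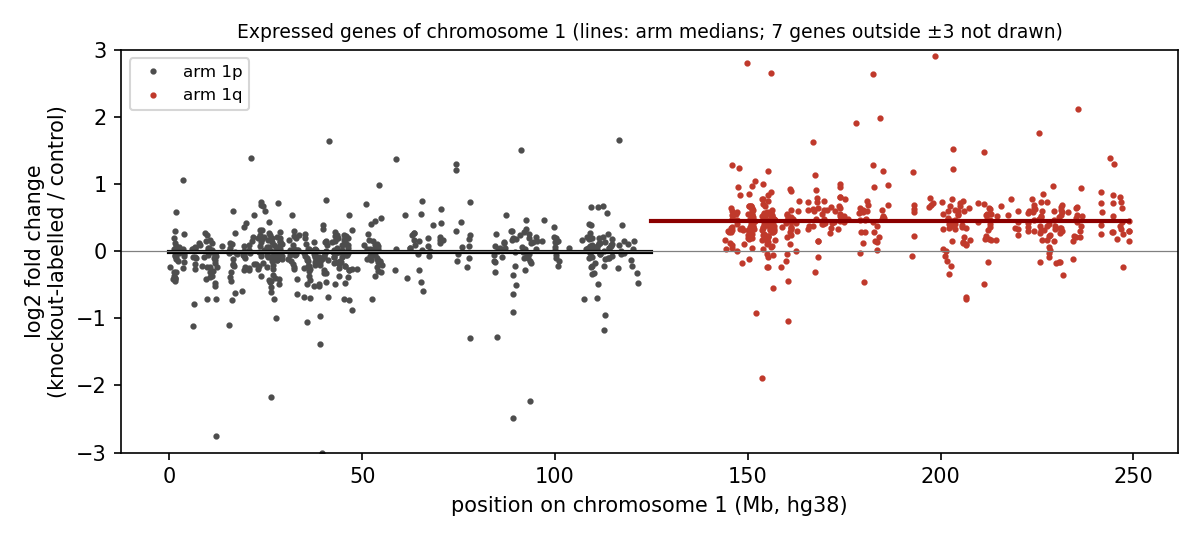
Each point is 1 expressed gene of chromosome 1, with its position in Mb on the horizontal axis and its log2 fold change between knockout-labelled and control libraries on the vertical axis; horizontal lines are arm medians. The 557 genes of 1p (grey) centre on -0.01 and the 440 genes of 1q (red) on 0.45, and 7 genes beyond a log2 change of 3 are not drawn.

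Close to SETD1B on 12q24.31, a pair of genes rose strongly. Of 25 tested genes within 1 Mb, SETD1B included, 8 rose and 9 fell by edgeR, of which 2 rose and 2 fell at least 2-fold. Over all genes tested, 60.4% passed and 10.5% passed with at least a 2-fold change. These counts alone therefore do not mark a local effect. P2RX7 fell from 1.43 ± 0.079 to 0.290 ± 0.21 CPM. BCL7A, a subunit of SWI/SNF chromatin remodelling complexes (chromosome 12, 122021884 to 122062044), rose from 40.5 ± 0.38 to 189 ± 5.9 CPM, and WDR66, which lies between it and SETD1B (chromosome 12, 121918592 to 122003919), rose from 14.98 ± 0.67 to 60.9 ± 3.0 CPM. TMEM120B fell from 23.7 ± 0.93 to 15.9 ± 0.57 CPM and KDM2B, an H3K36 demethylase gene, from 91.7 ± 3.2 to 71.2 ± 1.7 CPM. Of the 11 members tested of the neighbour list, 2 rose, 4 fell and 5 did not pass (adjusted over the list alone, 2 and 4). PSMD9, between SETD1B and WDR66, went from 30.8 ± 1.0 to 28.2 ± 1.8 CPM and did not pass. The list as a set did not pass camera (adjusted p = 0.627); its median log2 change was -0.06, its mean 0.17 and the camera direction down. LINC01089, which overlaps SETD1B, fell from 20.9 ± 1.3 to 8.95 ± 0.17 CPM, and because the strand setting of the counting is not given, reads of the overlapping pair cannot be assigned with certainty.

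**Figure D3:**
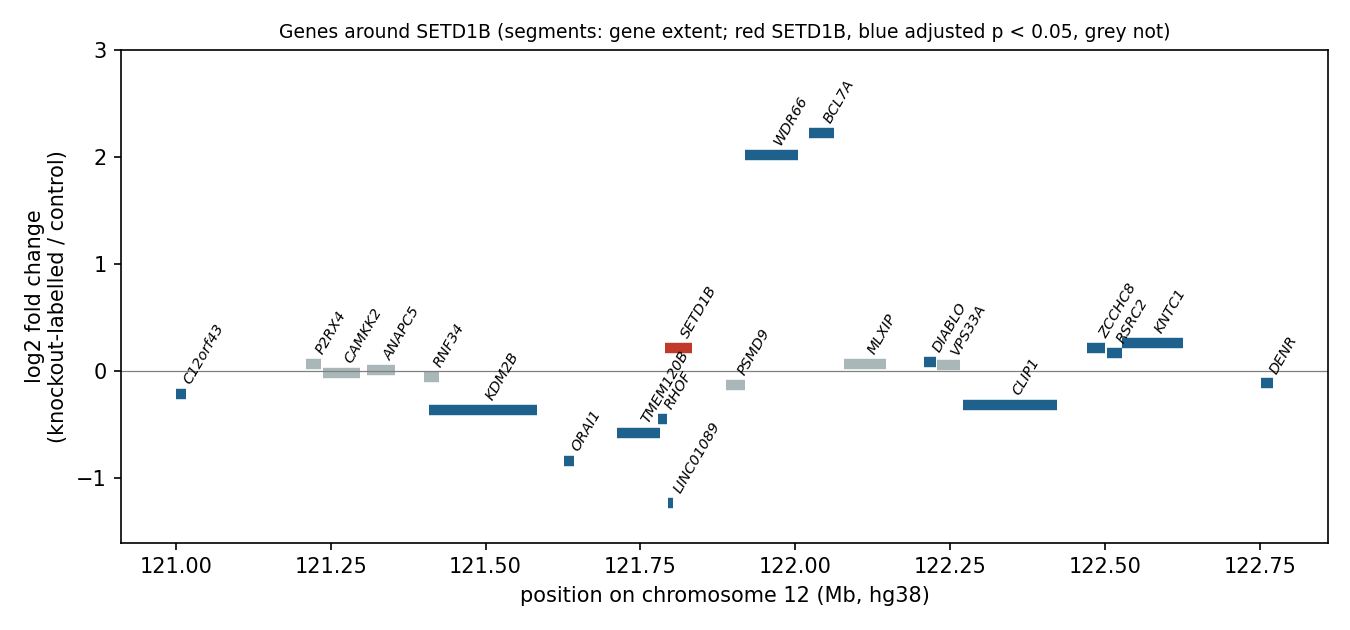
Segments show the extent of tested genes within 1 Mb of SETD1B on chromosome 12 (horizontal axis, Mb) at the height of their log2 fold change between knockout-labelled and control libraries. Only genes with a mean CPM of at least 5 are drawn, so P2RX7 is not shown. WDR66 and BCL7A stand at 2.02 and 2.22, SETD1B (red) at 0.22, and genes that did not pass the edgeR test are grey.

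Among 21 subunits of the complexes that methylate H3K4, 11 rose, 7 fell and 3 did not pass (adjusted over the list alone, 11 and 7); after the GC correction 10 rose and 3 fell by edgeR. The scaffold subunits RBBP5 and ASH2L rose from 57.5 ± 1.4 to 91.6 ± 3.4 CPM and from 136 ± 1.7 to 189.8 ± 4.8 CPM. PAXIP1, of the KMT2C/D complexes, rose from 109.7 ± 2.0 to 146 ± 2.3 CPM and PSIP1 from 260.1 ± 2.1 to 304 ± 7.0 CPM. RBBP5 lies on 1q. Of 5 enzymes that remove H3K4 methylation, 3 rose, 1 fell and 1 did not pass (adjusted over the list alone, 3 and 1). KDM1B rose from 89.2 ± 0.38 to 105 ± 1.1 CPM, KDM1A from 257 ± 1.7 to 295 ± 7.7 CPM and KDM5A from 185 ± 2.7 to 203 ± 5.1 CPM, while KDM5B fell from 68.7 ± 0.34 to 59.0 ± 3.2 CPM. Their log2 changes were 0.23, 0.20, 0.13 and -0.22, and after the GC correction 0.16, 0.21, 0.057 and -0.27. Neither list passed camera (adjusted p = 0.537 and 0.576).

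By camera with the preset correlation, genes of mitosis were higher as a set (adjusted p = 3.22e-04). With the correlation estimated for the list, 0.371, the list did not pass (camera adjusted p = 0.76). Of 28, 22 rose, 1 fell and 5 did not pass (adjusted over the list alone, 23 and 1). HMMR rose from 149 ± 1.7 to 225 ± 9.0 CPM, PRC1, a spindle midzone protein, from 284 ± 5.8 to 376 ± 7.0 CPM, ANLN, of the contractile ring, from 192 ± 1.5 to 251 ± 5.5 CPM and ASPM, a spindle pole protein encoded on 1q, from 433 ± 8.7 to 687 ± 44.7 CPM. The 1 gene that fell was AURKB, and MKI67 went from 1558 ± 11.2 to 1566 ± 59.9 CPM without passing. The median log2 change was 0.21; after the GC correction 20 rose and 0 fell by edgeR, with a median of 0.16 and a camera adjusted p of 0.00127. Replication genes showed no common direction: of 28, 7 rose, 10 fell and 11 did not pass (adjusted over the list alone, 7 and 10). GINS3 rose from 73.1 ± 2.3 to 97.9 ± 3.0 CPM, while LIG1, the replicative DNA ligase, fell from 196 ± 3.5 to 156 ± 8.8 CPM (camera adjusted p = 0.627). Of 18 replication-dependent histone transcripts tested, which poly(A) selection captures poorly, 1 rose, 6 fell and 11 did not pass (adjusted over the list alone, 0 and 2). HIST1H2AB fell from 0.402 ± 0.084 to 0.116 ± 0.085 CPM and HIST1H2AE from 0.893 ± 0.10 to 0.473 ± 0.12 CPM (camera adjusted p for the list = 0.197); the HIST1H2AE call was lost with DESeq2 (adjusted p = 0.062), and histone genes are near-identical copies whose reads may be shared. Of 25 genes of MYC-driven ribosome biogenesis, 7 rose, 9 fell and 9 did not pass (adjusted over the list alone, 7 and 9). NOP2 fell from 166 ± 1.1 to 136 ± 2.0 CPM and NOP56 rose from 401 ± 7.1 to 462 ± 4.6 CPM (camera adjusted p = 0.537).

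Interferon-stimulated genes were lower as a set by camera (adjusted p = 0.0136), but not with an estimated correlation (adjusted p = 0.475). Of 29 tested, 3 rose, 17 fell and 9 did not pass (adjusted over the list alone, 4 and 17). IFI44 fell from 15.6 ± 0.48 to 0.498 ± 0.17 CPM and the antiviral oligoadenylate synthetase OAS2 from 69.0 ± 1.4 to 28.7 ± 1.0 CPM. The guanylate-binding proteins GBP2 and GBP1 fell from 10.6 ± 0.33 to 1.87 ± 0.18 CPM and from 36.0 ± 0.34 to 19.2 ± 0.34 CPM. The 3 that rose were MX1, STAT2 and USP18.

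Neither list of antigen presentation genes passed the set test. Of 20 MHC class I genes, 1 rose, 12 fell and 7 did not pass (adjusted over the list alone, 1 and 12). NLRC5, the class I transactivator, fell from 288 ± 4.7 to 179 ± 16.1 CPM, the trimming peptidase ERAP1 from 128 ± 1.6 to 96.0 ± 2.7 CPM and CALR from 537 ± 12.2 to 452 ± 8.8 CPM (camera adjusted p = 0.0758). Of 16 MHC class II genes tested, 2 rose, 8 fell and 6 did not pass (adjusted over the list alone, 2 and 8). HLA-DQA1 fell from 134 ± 3.7 to 62.9 ± 2.7 CPM, HLA-DRB1 from 271 ± 8.9 to 156 ± 7.4 CPM and HLA-DRB5 from 36.1 ± 1.2 to 22.5 ± 1.5 CPM, while RFX5, on 1q, rose from 239 ± 1.8 to 300.1 ± 4.9 CPM. The class II camera adjusted p was 0.134, and with an estimated correlation over all genes 0.76. Without 1q genes it was 0.0182, but the 2 list members on 1q were the 2 that rose. That run therefore left 0 higher and 8 lower. After the GC correction the camera adjusted p was 0.242 for class II and 0.0652 for class I. HLA genes are polymorphic and resemble one another, so their individual counts are uncertain. Without control replicate 3 both MHC lists passed, at camera adjusted p = 0.0424, and without knockout replicate 3 the class I list did, at 0.0326, as it did on voom values, at 0.0449; with an estimated correlation the class I adjusted p was 0.475.

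Of 17 NF-kB targets, 4 rose, 12 fell and 1 did not pass (adjusted over the list alone, 4 and 12). TNFAIP3, the ubiquitin-editing inhibitor A20, fell from 451 ± 2.3 to 149 ± 7.6 CPM, CCR7 from 19.1 ± 0.37 to 0.393 ± 0.014 CPM and the co-stimulatory receptor CD40 from 3.33 ± 0.12 to 0.457 ± 0.029 CPM, while SOD2 rose from 121 ± 1.1 to 176 ± 2.7 CPM. The camera adjusted p was 0.0578, and it was 0.0424 without control replicate 3, 0.0326 without knockout replicate 3 and 0.0449 on voom values. In the other camera settings the NF-kB list did not pass. Among these the adjusted p was 0.148 with the stricter count filter, 0.119 after the GC correction and 0.475 with an estimated correlation. Of 11 checkpoint and co-stimulatory molecules, 2 rose, 5 fell and 4 did not pass (adjusted over the list alone, 2 and 5). CD48, on 1q, fell from 29.6 ± 0.17 to 1.33 ± 0.14 CPM, LGALS9 from 30.1 ± 1.8 to 13.4 ± 1.8 CPM, and CD47, the anti-phagocytic signal, rose from 163 ± 2.0 to 219.8 ± 9.7 CPM (camera adjusted p = 0.443).

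**Figure D4:**
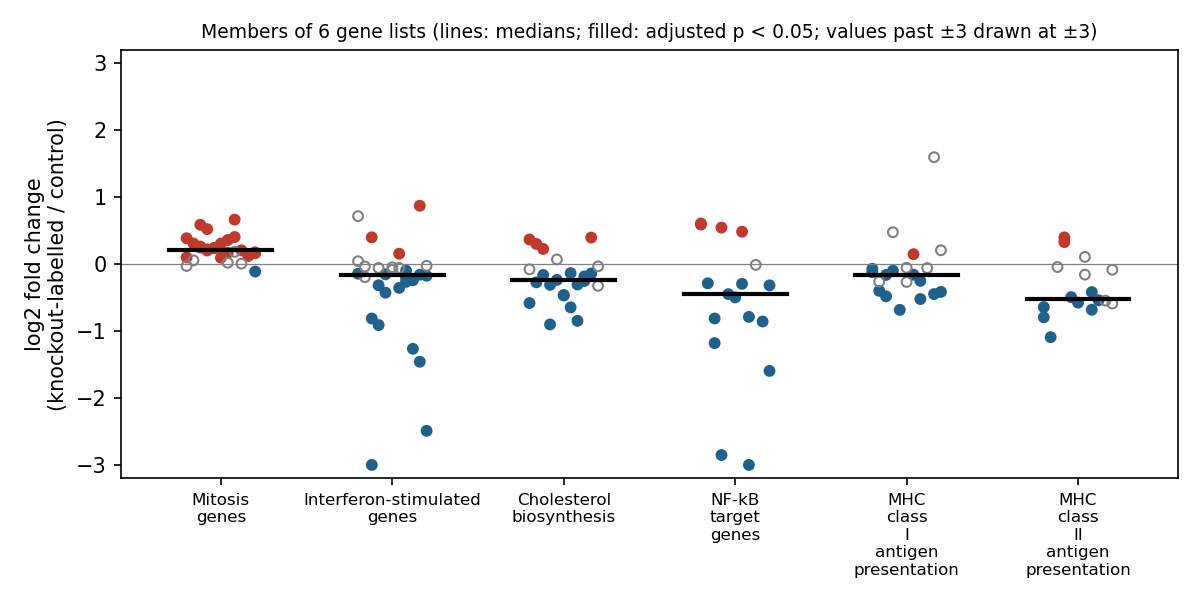
Points are the tested members of 6 gene lists, placed by log2 fold change between knockout-labelled and control libraries; filled points passed the edgeR adjusted p of 0.05, open points did not, black lines are medians, and values past 3 are drawn at 3. Mitosis genes have a median of 0.21 and interferon-stimulated genes of -0.16.

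B cell genes changed in both directions. Of 23 germinal centre genes, 10 rose, 12 fell and 1 did not pass (adjusted over the list alone, 10 and 12). The chemokine receptor CXCR4 rose from 66.7 ± 3.1 to 179 ± 6.2 CPM and the transcription factor BACH2 from 236 ± 4.4 to 431 ± 4.1 CPM, while SPIB fell from 114 ± 3.5 to 42.7 ± 2.2 CPM; the list's median log2 change was -0.10, its mean 0.08 and the camera direction down (adjusted p = 0.758). Of 15 plasma cell genes, 5 rose, 7 fell and 3 did not pass (adjusted over the list alone, 5 and 7). XBP1, the transcription factor of the secretory programme, fell from 535 ± 13.3 to 157 ± 5.4 CPM and FKBP11 from 24.0 ± 0.89 to 16.0 ± 0.15 CPM, and PRDM1 (BLIMP1) rose from 27.3 ± 1.6 to 45.0 ± 1.2 CPM (camera adjusted p = 0.537). Of 16 genes of the activated B cell-like lymphoma type, 5 rose, 9 fell and 2 did not pass (adjusted over the list alone, 6 and 9). CYB5R2 fell from 31.7 ± 0.75 to 2.14 ± 0.057 CPM and IL16 from 74.3 ± 1.8 to 39.5 ± 1.2 CPM, while BLNK rose from 72.7 ± 1.6 to 118 ± 1.3 CPM (camera adjusted p = 0.443). Of 23 genes of B cell identity and receptor signalling, 8 rose, 12 fell and 3 did not pass (adjusted over the list alone, 8 and 13). CD22, an inhibitory co-receptor, fell from 289 ± 2.6 to 123 ± 2.9 CPM and CD24 from 589.7 ± 15.2 to 373 ± 14.8 CPM, whereas the lineage factor PAX5 rose from 923 ± 18.6 to 1638 ± 38.9 CPM (camera adjusted p = 0.537). Of 13 genes known to depend on KMT2D in lymphoma, 5 rose, 5 fell and 3 did not pass (adjusted over the list alone, 5 and 5). The phosphatase gene DUSP1 fell from 120.2 ± 4.5 to 53.6 ± 4.0 CPM and BIRC3 rose from 16.2 ± 0.57 to 24.6 ± 0.22 CPM; the median log2 change was 0.09, the mean -0.36 and the camera direction down (adjusted p = 0.685).

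Cholesterol biosynthesis genes were lower as a set by camera (adjusted p = 0.0372), but not with an estimated correlation (adjusted p = 0.648). The call was also lost with the stricter count filter (camera adjusted p = 0.0502), with replicate number as a block (0.055), without knockout replicate 1 (0.0574) and after the GC correction (0.0563), and kept without 1q genes (0.00294). The median log2 change was -0.24 and after the GC correction -0.21, with 4 higher and 15 lower in each. Of 23, 4 rose, 15 fell and 4 did not pass (adjusted over the list alone, 4 and 15). DHCR7, which completes cholesterol synthesis, fell from 65.0 ± 2.1 to 34.8 ± 3.6 CPM, CYP51A1 from 127 ± 3.3 to 85.2 ± 2.4 CPM, HMGCS1 from 233 ± 4.5 to 169.5 ± 8.0 CPM and SC5D from 53.2 ± 1.5 to 38.4 ± 1.7 CPM. The 4 that rose were FDPS, PMVK, TM7SF2 and HSD17B7, and 3 list members lie on 1q. Of 27 genes of glycolysis and the hypoxia response, 5 rose, 14 fell and 8 did not pass (adjusted over the list alone, 5 and 14). The hexokinases HK2 and HK1 fell from 119 ± 1.7 to 87.1 ± 1.2 CPM and from 152 ± 5.5 to 112 ± 5.5 CPM, the glucose transporter SLC2A1 fell from 61.3 ± 0.88 to 43.7 ± 2.6 CPM, and MXI1 rose from 20.5 ± 0.45 to 28.4 ± 1.3 CPM (camera adjusted p = 0.197).

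Of 26 genes of the unfolded protein and amino acid stress responses, 10 rose, 9 fell and 7 did not pass (adjusted over the list alone, 10 and 9). EDEM1, of endoplasmic reticulum-associated degradation, fell from 823 ± 33.4 to 348 ± 7.3 CPM, while the stress transcription factor DDIT3 (CHOP) rose from 21.1 ± 1.0 to 41.6 ± 3.9 CPM and PSAT1 from 331 ± 7.2 to 401 ± 2.9 CPM (camera adjusted p = 0.753). Of 29 oxidative phosphorylation subunits, 8 rose, 6 fell and 15 did not pass (adjusted over the list alone, 8 and 5). SDHC, on 1q, rose from 42.2 ± 0.82 to 79.0 ± 3.6 CPM, and NDUFA9 fell from 155 ± 1.8 to 140.3 ± 3.1 CPM; the median log2 change was -0.01, the mean 0.06 and the camera direction up (adjusted p = 0.627).

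Of 14 BCL2 family genes, 4 rose, 7 fell and 3 did not pass (adjusted over the list alone, 4 and 7). The pro-apoptotic gene BIK fell from 22.8 ± 1.5 to 5.01 ± 0.44 CPM and BCL2L11 (BIM) fell 1.76-fold, and HRK and BMF, also pro-apoptotic, rose from 17.9 ± 1.3 to 38.6 ± 1.5 CPM and from 0.864 ± 0.070 to 5.36 ± 0.67 CPM (camera adjusted p = 0.537). Of 22 p53 targets, 9 rose, 6 fell and 7 did not pass (adjusted over the list alone, 9 and 6). BTG2, on 1q, rose from 25.9 ± 1.3 to 74.9 ± 1.1 CPM and TP53INP1 from 4.19 ± 0.47 to 10.3 ± 0.63 CPM, while MDM2, the ubiquitin ligase of p53, fell from 442 ± 0.45 to 253 ± 15.1 CPM (camera adjusted p = 0.57). Of 17 genes of lymphocyte adhesion and migration, 6 rose, 10 fell and 1 did not pass (adjusted over the list alone, 6 and 10). The adhesion receptor CD44 fell from 2.15 ± 0.48 to 0.123 ± 0.026 CPM and ICAM3 from 54.4 ± 1.2 to 23.9 ± 2.8 CPM (camera adjusted p = 0.537).

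Markers of other cell types did not move together. Of the T and NK cell markers 3 were tested, too few for the set test: IL7R fell, GZMA (granzyme A) fell from 6.01 ± 0.15 to 0.219 ± 0.11 CPM and ZAP70 rose from 10.8 ± 0.26 to 16.9 ± 2.9 CPM. Of 5 myeloid markers, 2 rose, 2 fell and 1 did not pass (adjusted over the list alone, 2 and 2). CD33 fell from 15.6 ± 0.22 to 3.76 ± 0.017 CPM and LYZ (lysozyme) from 8.49 ± 1.2 to 1.30 ± 0.26 CPM, and VCAN and CD14 rose from 0.0762 ± 0.086 to 1.13 ± 0.071 CPM and from 0.137 ± 0.026 to 0.472 ± 0.13 CPM; the median log2 change was -0.15, the mean 0.15 and the camera direction down (adjusted p = 0.627). Of the stromal and epithelial markers 0 had enough counts to be tested. Mitochondrially encoded transcripts were not analysed here. Over all 25 lists tested, 3 passed camera with a preset correlation of 0.01. With an estimated correlation 0 passed, and 2 had an unadjusted p under 0.05. Of the 10 splits of the libraries into groups of 3, 3 gave at least as many lists past camera, the real split included. Members named as exceptions within a list (AURKB, MKI67, MX1, STAT2, USP18, PSMD9, P2RX7, LINC01089, FDPS, PMVK, TM7SF2 and HSD17B7) were chosen after their values were seen.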

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

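Alternatives were fixed before the data were examined, except the correction for GC content, the run without genes of identical counts and the run without 1q genes, which were chosen after seeing the data. The count of 7957 changed genes ranged from 6287 (adjusted p of 0.01) to 8514 (GC correction) over whole-set alternatives and from 6977 to 8528 with 1 library left out. The share of changed genes that were lower, 49.7%, ranged from 48.2 to 52.2%. With a CPM of at least 5 in 3 libraries the 2-fold genes fell from 1387 to 569, 233 higher and 336 lower; fewer low-count genes were tested there. SETD1B stayed higher in every run that tested it, by 0.17 to 0.43 on the log2 scale. Deviations of libraries with the same replicate number correlated little (0.03, 0.01 and 0.06). Still, 5 of 6 libraries correlated best with their own number, so a weak pairing is possible. The replicate block gave 8190 changed genes, and of all list calls it ended that of cholesterol biosynthesis (camera adjusted p = 0.055). Lists past the threshold numbered 3, and 2 to 6 with 1 library left out (6 without control replicate 3, 5 without knockout replicate 3 and 2 without knockout replicate 1), 0 with an estimated correlation, 21 with fry, which tests a list without comparing it with other genes, and 5 on voom values (the 3 with MHC class I and NF-kB targets). Under fry the neighbours of SETD1B (adjusted p = 0.000234) and germinal centre genes (adjusted p = 0.00818) turned to up; the cause was not tested. The GC correction turned SETD1A to 9.0e-05 and KMT2D to 0.018. Of 121 named genes 116 kept their call and direction in every run that tested them; the others were SETD1A, KMT2D, HIST1H2AE, HIST1H2AM and HIST1H3B. The planned overlap with the authors' calls could not be run. Small effects may be missed: at 1.2-fold with 3 libraries per group, 46% of simulated changes were recovered. In that simulation 12970 of 13170 genes were unchanged, whereas 60.4% of genes were called in the data. The adjusted p depends on this share, so the 46% does not give the share of small effects missed here.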

Other observations

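All tests in this part were chosen after the patterns were seen, except those of GC slopes between libraries and of the GC slope without 1q genes, whose criteria were written before their values were computed. Lists in this and the next paragraph were drawn up after their leading genes had been noticed in these libraries. Neither their direction nor their camera p-values are therefore independent evidence, and the adjustment covers these 4 lists alone. Most genes of a list of early B cell development fell. Of 18 tested, 14 fell and 4 rose by edgeR. The recombinase genes RAG1 and RAG2 fell from 1410.1 ± 28.2 to 358 ± 6.3 CPM and from 302 ± 8.5 to 153 ± 5.1 CPM, and DNTT, the terminal transferase that adds bases at recombination junctions, from 898 ± 3.6 to 277 ± 13.7 CPM. The surrogate light chain genes IGLL1 and VPREB1 fell from 778 ± 36.2 to 125.4 ± 18.0 CPM and from 314 ± 2.7 to 139 ± 14.01 CPM, and the receptor subunit CD79A from 126 ± 2.0 to 20.2 ± 2.9 CPM. The 4 that rose were BLNK, VPREB3, CD79B and MME; after the GC correction 3 rose and 14 fell, and the MME log2 change went from 0.14 to 0.036 (edgeR adjusted p = 0.165). Over the 4 added lists the camera adjusted p was 2.10e-04, and with an estimated correlation the adjusted p = 0.12.

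Genes of the leukocyte actin cytoskeleton were lower as well: of 45 tested, 32 fell and 6 rose by edgeR. ACTB fell from 6525 ± 151 to 3882 ± 308 CPM, WIPF1, a partner of the Wiskott-Aldrich protein, from 357 ± 3.3 to 118 ± 5.0 CPM, CORO1A from 320.2 ± 17.9 to 118 ± 22.3 CPM and the myosin MYO1G from 50.4 ± 2.0 to 12.7 ± 1.3 CPM. FMNL1, a formin, fell from 46.9 ± 2.3 to 5.69 ± 1.4 CPM and ZYX from 57.1 ± 1.9 to 7.66 ± 1.6 CPM, while the membrane linker EZR rose from 493 ± 6.4 to 1023 ± 23.4 CPM. The camera adjusted p was 1.88e-05, and with an estimated correlation the adjusted p = 0.12. Of 35 SR and hnRNP splicing factors, 20 rose and 4 fell (camera adjusted p = 0.0154, and 0.463 with an estimated correlation); after the GC correction 13 rose and 8 fell, and the camera adjusted p was 0.358. Of 25 clustered protocadherins, 22 rose and 0 fell (camera adjusted p = 2.78e-09, and 0.18 with an estimated correlation). All of those that rose belong to the gamma cluster, whose genes share their final exons, so they amount to a single locus; PCDHGC5 rose from 2.20 ± 0.083 to 3.98 ± 0.17 CPM.

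The block of higher genes on 1q is a pattern that a copy-number difference between the lines may account for. GC content does not account for it, because the median log2 change of the 440 genes was 0.43 after the GC correction. In the 10 windows of 10 Mb with at least 15 expressed genes the GC-corrected median was 0.33 to 0.47, 90.9% of the genes lay above the median of all other genes, and 229 such windows elsewhere ranged from -0.27 to 0.22, consistent with a gain of the arm in the line labelled knockout as a hypothesis; windows with fewer genes were not used. Whether loss of SETD1B raised 1q genes without a gain was not tested, and DNA was not analysed here.

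GC-rich genes were lower in the libraries labelled knockout: the median log2 change went from 0.10 in the decile of genes with the lowest GC content to -0.33 in that with the highest. Gene length does not account for it, since 96.8% of the slope was kept with length in the fit, nor does 1q, since 97.9% was kept without its genes. GC slopes were fitted to each library's deviation from the mean of all libraries, so they are relative and not a library's own slope. Those of the 3 knockout-labelled libraries were -0.08, -0.16 and 0.00028 log2 units per 10 percentage points, against 0.06, 0.08 and 0.10 in control libraries. The difference between group means was 1.01 times the larger range within a group. A technical GC bias that varies between libraries may therefore contribute, and a biological effect of SETD1B loss on GC-rich genes was not tested.

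Expression of 13 genes was all or none: at most 3 counts over 1 group and at least 300 over the other, with 6 silent in the libraries labelled knockout (among them ZNF518B, LCP2 and NLGN4X) and 7 silent in control (among them TFPI, DAPK1 and SLC25A27). For 9 genes, neighbours with a mean CPM of at least 5 lay within 500 kb. Of these 23 neighbours, 0% lay under 10% of their level in the other group. For these 9 genes this argues against loss of a segment that reaches those neighbours. The nearest such neighbour of ZNF518B, LCP2, ATXN1 and NLGN4X lay 323, 163, 135 and 477 kb away. A loss confined to the gene, or ending before these neighbours, was not tested. Loss of neighbours under that mean CPM was not tested either. For the other 4 genes no neighbour reached a mean CPM of 5, so loss of a segment cannot be told apart. With 1 cell line per group, divergence of the cell populations apart from SETD1B cannot be told apart from an effect of SETD1B.

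The 6 libraries allow 10 splits into groups of 3, too few for a share under 0.05. The real split gave 7957 genes and 1387 at 2-fold, each matched by 1 of the 10 splits (the real one), with a highest other count of 0 by edgeR. At an unadjusted p under 0.05 the 9 other splits gave 29 to 207 genes and the real one 8516. Each of the 9 other splits mixed libraries of both groups, so the difference between groups entered its spread and held its calls down. Their counts are therefore no baseline for groups without a difference, and no conclusion is drawn from them. For gene lists past camera the real split gave 3, the highest other 4, and 3 of the 10 splits gave at least as many.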
